A study of Homo sapiens with 2 samples.

How the data were processed

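One H4R3me2a immunoprecipitation library and 1 input library from untreated HCT116 cells were compared, per the labels. Cells were cross-linked with formaldehyde, chromatin was sheared by sonication, and libraries were sequenced as paired-end reads. The submitters' processing notes name Bowtie2, an aligner, MACS2, a peak caller, deepTools and the genome build GRCh38. Versions, parameters and read filters are not given in the sources used here. The labels' design names 1 input library as the control, and the comparison of the peak list is H4R3me2a against that input, so the peaks come from single libraries and not from pooled replicates. The number of reads in each library is not given in the sources used here, and depth is described by the pileup alone.

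The deposited peak table gives for each peak its position, width and summit, the signal at the summit as a pileup of fragments (whole numbers, not normalized), the fold enrichment, and the −log10 of a p-value and a q-value. Per the file headers, the fold is a ratio of the pileup over the local background, and each value is the peak's own, from the authors' caller. The values were used only to describe, rank or filter peaks within the list. The deposited interval list repeats the same fold, p and q for all 33353 peaks, with a score that is the −log10 q multiplied by 10 and truncated by the authors' caller. Its starts lie 2 bp before those of the table in every peak, and the table's 1-based coordinates were used. A summary deposited by the authors gives 33353 peaks, a total length of 7529923 bp and a median of 186 bp.

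The background at each summit was recovered as (pileup + 1) / fold − 1. The recovered value and the pileup gave back the deposited −log10 p as a Poisson tail to within 0.05 in all 33353 peaks. The lowest recovered background, 0.698 fragments, was shared by 2694 peaks (8.08%), and the commonest levels were spaced by 0.512 fragments. No peak ended beyond a chromosome of the GRCh38 sequence used here, which was paired with GENCODE release 44.

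Peaks on chromosomes 1 to 22 and X entered all comparisons, and 4 peaks on mitochondrial DNA are described apart. Each summit received 1 class, in the order promoter (within 1 kb of a TSS of any transcript of a protein-coding gene), 5' UTR, 3' UTR, coding sequence, exon of a non-coding gene, intron and intergenic. Shares were set against 1000 random placements in sequence other than N on the same chromosome. As additions made after the data were first examined, though before their own results were seen, 100 placements were matched on chromosome and GC content of the 200 bp on either side (bins of 2%), and another 100 also on CpG count. Ranges of placements are the lowest and highest. Intervals of shares and of ratios made from them are exact (Clopper-Pearson) at 95%, and intervals of medians use binomial ranks. The profile around TSSs used the canonical transcript of each of 19970 protein-coding genes and was also chosen after seeing the data. Its expected line gave each position the peak rate of its GC content over the genome.

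Gene lists were fixed before the data were examined, as were the classes, windows, placements, the rule for named genes and the alternatives, except those named as added. All 585 symbols of the fixed lists were found in the annotation, and 2 lists, the olfactory receptors and the ZNF genes, were taken from it by symbol. For each list the share of members with a promoter peak was given as its percentile among 10000 random lists of the same size, drawn from protein-coding genes matched on the CpG observed to expected ratio of the 500 bp on either side of the gene's 5' end (10 bins). Genes and peaks of a single library are not replicates, so no p-value was computed across them, and percentiles describe this peak list only. Permutation p-values were computed only for a correlation over the 23 chromosomes of the same peak list, and they do not cover replicate error either.

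The rule for named genes took the genes with one of the 10 highest-fold peaks at a promoter, those of the 5 widest promoter peaks, the 5 highest-fold peaks more than 10 kb from every protein-coding TSS, and up to 4 members of each list with the highest-fold promoter peak. All members of the PRMT family, EGFR and TNS1 were named whatever their values. Some genes that the rule took are not reported here. A gene had a promoter peak if a summit lay within 1 kb of any of its annotated TSSs, which includes TSSs inside the gene.

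Alternatives were stricter peak sets (−log10 q of 5 or more, fold of 4 or more, and the 50% of peaks with the higher −log10 q), merging of peaks less than 1 kb apart, promoter windows of 500 bp and 3 kb, other rules of overlap, gene 5' ends alone, expectation by gene number, and other matching of lists. Copy number in the genome was counted for 32-mers around each summit, by exact match, and for the 10 highest pileups, 500 sampled peaks and 500 random positions also with BLAST 2.17.0 (90% identity over 80% of the sequence within 200 bp). The steps were tested on simulated data. Among 6000 simulated peaks on chromosomes 20 to 22 with a planted promoter share of 30%, a share of 30% was recovered. For 6000 peaks placed by GC content alone, the promoter share was 4.91 times that of unmatched placement and 1.02 times that of GC-matched placement. For gene list shares, 6.00% of 200 null lists from 2000 simulated genes fell outside the central 95%, and a planted list stood at percentile 100. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.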

Results

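The data describe where asymmetric dimethylation of arginine 3 on histone H4 (H4R3me2a), a mark placed mainly by the arginine methyltransferase PRMT1, lies in the genome of HCT116 cells, an established human colorectal carcinoma line. Untreated cells were cross-linked, and 1 chromatin immunoprecipitation library made with an antibody against H4R3me2a was set against 1 library of input DNA. There were no replicates, so no value below has a replicate check, and the intervals given cover counting error only. The authors' list held 33353 peaks, 33349 of them on chromosomes 1 to 22 and X. These covered 7.50 Mb, or 0.257% of the sequence that is not N, in narrow intervals with a median width of 185 bp and a range of 126 to 2432 bp.

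The peaks rested on few fragments. The median pileup at the summit was 10 fragments (quartiles 8 and 12), over a median background of 1.54 fragments, and 59.5% of peaks (95% exact interval 59.0 to 60.04%) had a pileup of 10 or fewer. The authors' fold enrichment had a median of 4.18 (quartiles 3.70 and 4.73), and 1172 peaks (3.51%) reached a fold of 6. A −log10 q of 5 or more was given to 1280 peaks (3.84%).

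The question of which parts of the genome carried the mark was addressed by placing each summit in the annotation. Peaks were concentrated at promoters, taken as the sequence within 1 kb of an annotated transcription start site (TSS) of a protein-coding gene, which held 10105 summits or 30.3% (29.8 to 30.8%). Random placement of the same number of summits on the same chromosomes put 6.12% there (range of 1000 placements 5.78 to 6.54%), so promoters held 4.95 times the random share. Coding sequence outside promoters held 4.35% of summits, 5.45 times the random share, and the 3' UTRs held 4.62%, 2.42 times. The 5' UTRs outside promoters held 78 summits (0.234%, 3.28 times random) and exons of non-coding genes 3.33% (1.5 times random). Introns held 40.1% and intergenic sequence 17%, both below random placement, with ratios of 0.761 and 0.471.

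Part of this distribution followed the base composition of the sites. Among placements matched on chromosome and GC content, promoters took 22.5% of summits (22 to 23%), which left an observed share 1.35 times higher. The other exonic classes of protein-coding genes had similar excesses over matched placement, 1.56 times for 5' UTRs, 1.38 for 3' UTRs and 1.29 for coding sequence, while non-coding exons fell below 1 to 0.854. Intergenic sequence stayed below its matched share at 0.692, and introns were at 0.954. The placements were not kept out of repeated sequence, where peaks were rarer, and the part of this in the ratios was not tested. The promoter share depends strongly on the set of TSSs, since a protein-coding gene has a median of 5 annotated TSSs, many inside the gene. With the 5' end of each gene alone it was 11.9%, or 6.51 times the 1.82% expected by random placement. That expectation was not matched on GC content, so 6.51 compares with the unmatched 4.95 for all TSSs and not with the matched ratios.

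**Figure D1:**
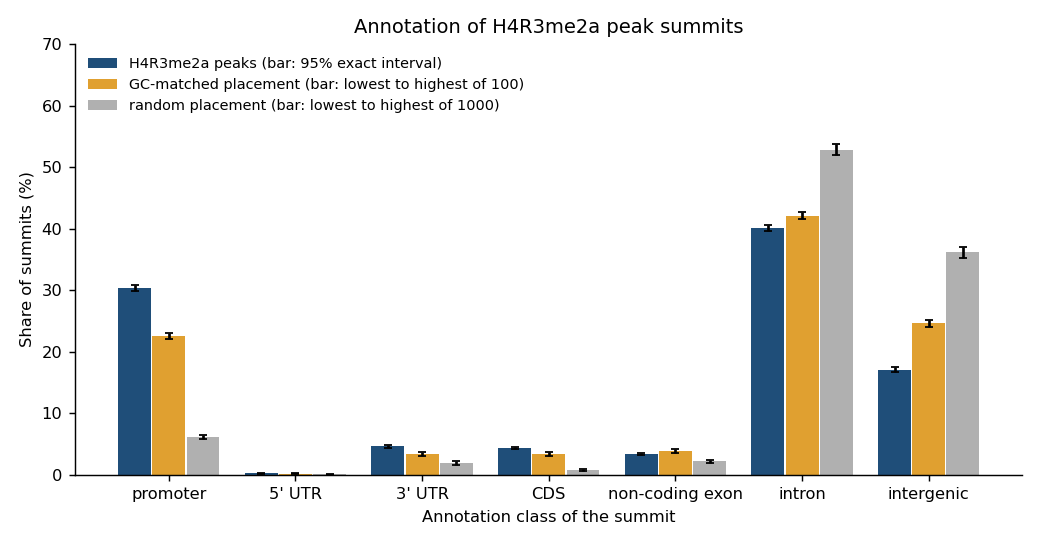
Share of peak summits (y axis, percent) in each annotation class (x axis) for the observed H4R3me2a peaks, GC-matched placements and unmatched random placements, with error bars as defined in the legend. Promoters held 30.3% of summits, against 22.5% with GC matching and 6.12% without.

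The median fold was 4.26 at promoters (interval of the median 4.26 to 4.28) and 4.15 in intergenic sequence (4.12 to 4.19), and it was lowest in 3' UTRs at 4.08. It was 4.11 in 5' UTRs, 4.13 in coding sequence, 4.23 in non-coding exons (4.15 to 4.31, which includes the promoter median) and 4.12 in introns. Promoter peaks were wider, with a median of 205 bp against 174 bp in intergenic sequence. A fold of 6 or more was reached by 5.59% of promoter peaks and 2.52% of intergenic peaks. The fold of called peaks depends on the background, with a median of 4.60 where this was under 0.8 fragments and 3.46 at 2.8 to 3.3. The classes differed in background (medians of 1.19 in intergenic sequence, 1.54 at promoters and 1.78 in 3' UTRs), so their median folds do not compare the strength of the mark.

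Several of the 10 peaks with the highest fold lay in promoters, among them those at SMAP2 (chromosome 1, 40373775 to 40374278, fold 10.0) and where the promoters of GDAP1 and JPH1 overlap (chromosome 8, 74320990 to 74321189, fold 9.96). Others were at DYNC1H1, the heavy chain of cytoplasmic dynein, and HDAC2, a histone deacetylase, both with a fold of 9.43 from 15 fragments. The peaks at SMAP2, DYNC1H1 and HDAC2 had the lowest recovered background, 0.698 fragments. Summits lay 266 bp from the nearest TSS at SMAP2, 7 bp at GDAP1, 430 bp at DYNC1H1 and 129 bp at HDAC2. The 5 widest promoter peaks were at FASN, the fatty acid synthase (1547 bp, fold 5.69), STK11, a tumour suppressor kinase (1470 bp, fold 4.59), INF2 (1425 bp, fold 5.87), UNC13D (1365 bp, fold 5.87) and TUBB3 (1249 bp, fold 3.39).

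The 5 highest-fold peaks more than 10 kb from any protein-coding TSS had folds of 9.29 to 16.8. A pair of neighbouring intergenic peaks on chromosome 1, at 144102434 to 144102737 and 144103583 to 144104143, had folds of 16.8 and 11.3 with pileups of 93 and 120. The summit of the former lay 131 kb from the nearest protein-coding TSS, that of FAM72C, in sequence whose central 32-mers occurred 10 times in the genome. An intergenic peak on chromosome 2 (87417968 to 87418492) had a fold of 11.2. The remaining peaks lay in introns of the pseudogene ESPNP (chromosome 1, 16699589 to 16699908, fold 10.4) and of a long non-coding RNA gene (chromosome 14, 76921954 to 76922446, fold 9.29).

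Around canonical TSSs, summits lay on the transcribed side. Over 19970 protein-coding genes, 2310 summits fell 100 to 600 bp downstream of the canonical TSS and 517 fell 100 to 600 bp upstream, a ratio of 4.47 (95% exact interval 4.06 to 4.92). The highest 100-bp bin, from 400 to 500 bp downstream, held 590 summits, and the 100 bp directly upstream of the TSS held 66. At 2 to 3 kb from the TSS the mean was 78.5 summits per bin upstream and 121 downstream. GC content was higher downstream (60.5%) than upstream (55.2%), and summits placed by GC content alone would have given 1428 downstream and 1019 upstream. By bin, summits were fewer than GC content alone would give from 600 bp upstream to 200 bp downstream. In the 100 bp directly upstream, 66 stood against 324. They were more numerous at 400 to 500 bp downstream (590 against 258). In the outermost bins summits also exceeded the GC-based number, with 80 against 46.9 upstream and 114 against 59.0 downstream. An excess over GC content was thus not particular to promoters, and directly upstream of the TSS there was a deficit.

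**Figure D2:**
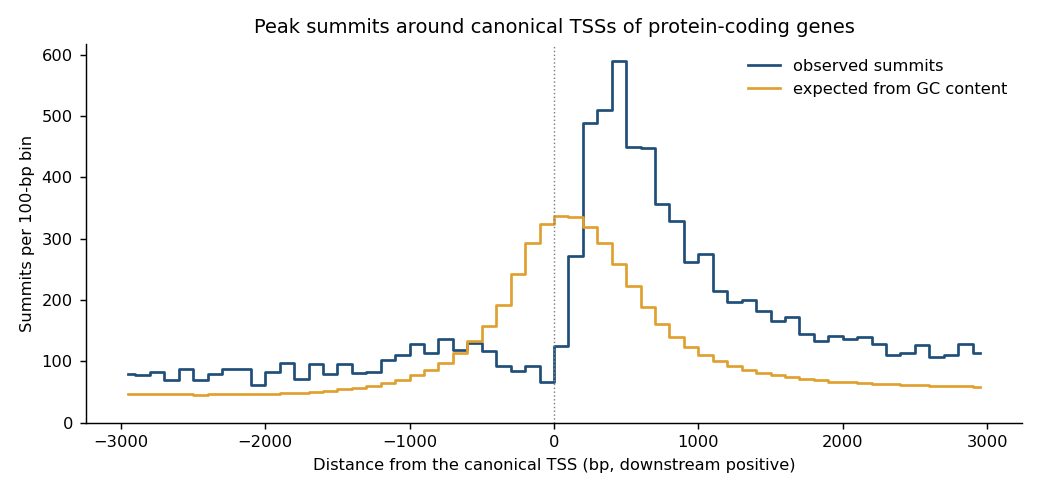
Number of peak summits per 100-bp bin (y axis) by distance from the canonical TSS in bp (x axis, downstream positive), observed and predicted from GC content. The observed line dips to 66 summits just upstream of the TSS and is highest 400 to 500 bp downstream, at 590.

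Peaks lay in GC-rich sequence. The 200 bp on either side of the summits had a mean GC content of 59.3% (SD over peaks 7.26) against 42.7% for random positions, and a CpG observed to expected ratio of 0.350 against 0.230. Sequence of under 40% GC makes up 50.5% of the genome and held 60 peaks, or 0.0408 per Mb. The density was 3.35 peaks per Mb at 40 to 50% GC, 43 at 50 to 60%, 227 at 60 to 70%, 222 at 70 to 80% and 112 above 80%.

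**Figure D3:**
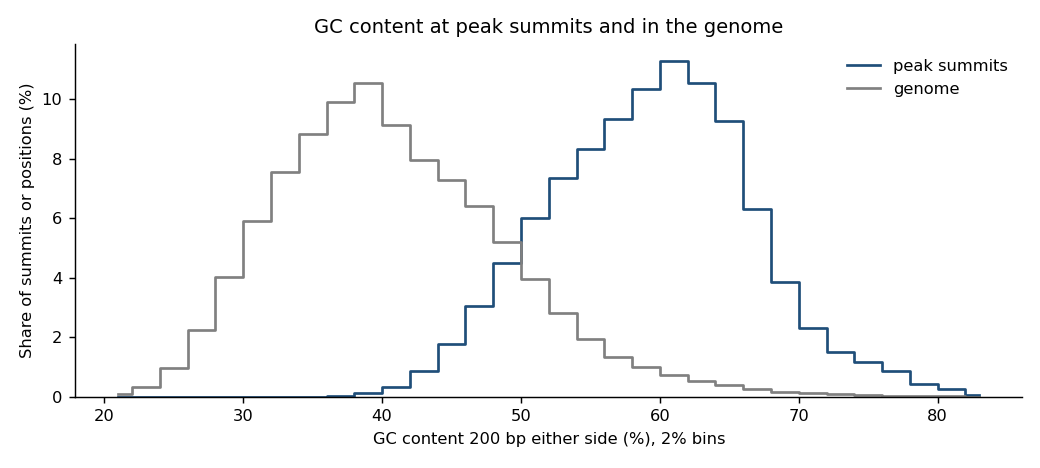
Share of peak summits and of genome positions (y axis, percent) by GC content in the 200 bp on either side (x axis, bins of 2%). The peaks have a mean of 59.3% GC, and random positions a mean of 42.7%.

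Peak density differed between chromosomes. Chromosome 19, the most gene-rich, had 59.7 peaks per Mb, 5.21 times its share by length (5.05 to 5.38), and chromosome 17 had 45.7 per Mb, 3.99 times (3.87 to 4.11). Chromosomes 22 and 16 followed at 3.33 and 2.67 times. The X chromosome had 177 peaks, 0.0998 of its share by length (0.0856 to 0.116), and chromosome 18 had 0.277. The differences were smaller once GC content was taken into account: chromosome 17 was then highest at 1.82 (1.77 to 1.88), chromosome 19 was at 1.57, chromosome 16 at 1.37 and chromosome 22 at 1.11, while chromosomes 18 and X stayed low at 0.457 and 0.175. The median background at the peaks also differed by chromosome, from 0.732 fragments on X to 2.05 on chromosome 17 and 2.07 on chromosome 8. The value of X lies close to the lowest recovered background, 0.698 fragments. Where the background was under 0.8, the lowest called fold was 3.35. The low count on X does not by itself show absence of the mark, and no ratio was adjusted for the number of DNA copies.

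**Figure D4:**
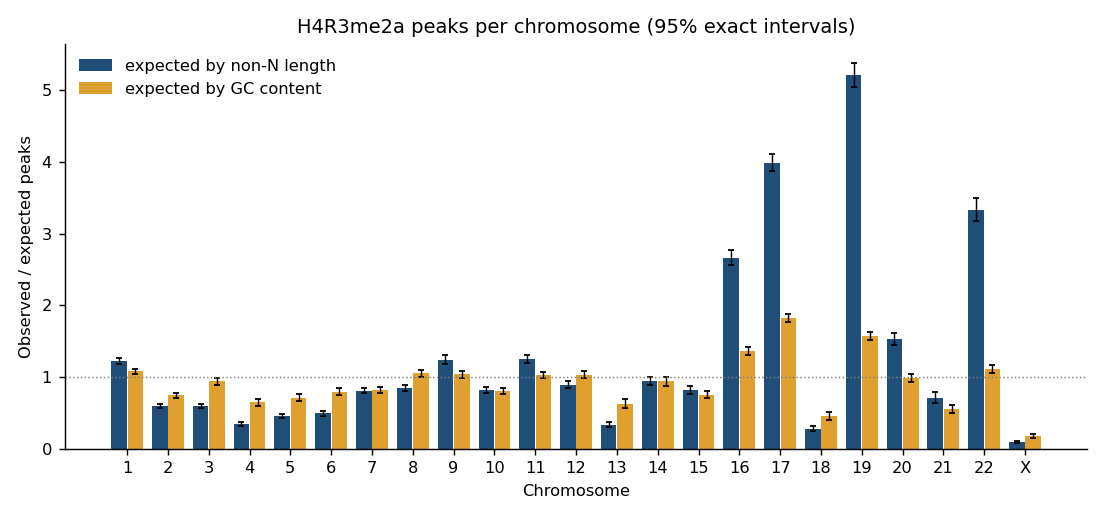
Ratio of observed to expected peaks (y axis) for each chromosome (x axis), with the expected number taken from the length without N or from GC content, and 95% exact binomial intervals. Chromosome 19 has the highest ratio by length at 5.21, chromosome 17 the highest by GC content at 1.82, and X the lowest by both.

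At the level of genes, 6311 of 19970 protein-coding genes (31.6%, 31 to 32.3%) had a promoter peak, and 2337 had more than 1. The share rose with promoter CpG content, from 12.2% in the lowest of 10 equal bins of genes to 41.6% in the highest. The count fell to 3829 genes when the 5' end of each gene alone was used. Within the PRMT family itself, 2 of 9 members had a promoter peak. PRMT1 had 4, and the one with the highest fold, 5.05, lay near an internal TSS (chromosome 19, 49687166 to 49687425). The summit of that peak lay 11569 bp from the 5' end of the gene. CARM1, which methylates arginines of histone H3, had a peak of fold 3.18 near an internal TSS and 12 peaks in its body. The summit of the promoter peak lay 48697 bp from the 5' end of that gene. PRMT2, PRMT3, PRMT5, PRMT6, PRMT7, PRMT8 and PRMT9 had none at a promoter. The family's share, 22.2%, stood at percentile 20.5 among 10000 random lists of the same size matched on promoter CpG content.

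Glycolysis genes carried the mark at their promoters more often than matched genes. Of 18 members, 13 (72.2%, 46.5 to 90.3%) had a promoter peak, against a mean of 31.9% in matched random lists (percentile 99.98). The highest folds were at HK1, a hexokinase (fold 6.56), SLC2A1, a glucose transporter (6.42), GPI, the glucose-6-phosphate isomerase (6.31), and ENO2, an enolase (6.18). Their pileups ran the other way, from 11 fragments at HK1 to 18 at ENO2, over backgrounds of 0.829 and 2.07. The folds therefore do not rank the strength of the mark. Of the genes named, only SLC2A1 had its peak, 180 bp from the 5' end, within 1 kb of the start of the gene. The list's genes had more sequence near a TSS than protein-coding genes in general (medians of 9.84 and 4.63 kb), and with that length also matched, random lists had a mean of 40.9% (percentile 99.6). The excess depended largely on internal TSSs: with gene 5' ends alone the share was 27.8% against a matched mean of 19.1%, inside the matched range (percentile 82.1).

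Promoter peaks were rarer than in matched genes in 3 groups. None of 53 replication-dependent histone genes had one, which allows a share of up to 6.72%, while matched lists had a mean of 38.4%. Olfactory receptor genes had 2 of 400 (0.5% against 17.5%), at OR1F1 (fold 4.54) and OR3A2 (3.95). Zinc finger genes of the ZNF series had 65 of 476 (13.7% against 34.0%). Their highest folds were at ZNF697 (6.51, a peak shared with PHGDH), ZNF584 (6.48), ZNF622 (5.93) and ZNF414 (5.87). All 3 lists stood at percentile 0, and so they did with matching on promoter GC content (means of 18.8%, 9.45% and 31.2%) or on CpG and the length of promoter sequence (25.1%, 8.06% and 31.6%). The histone genes were inside the matched range, at percentile 6, among peaks with a −log10 q of 5 or more, where matched lists also had a mean of 3.94%. With matching on CpG and chromosome the means were 30.3%, 17.5% and 39.4%, again at percentile 0. Position within a chromosome was not matched, and genes of a list that lie close together are not independent draws. A region poor in peaks as a whole was therefore not told apart from its genes.

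The other 17 lists lay inside the central 95% of matched random lists. Their members are named in order of fold, which depends on the background and does not rank the strength of the mark. The promoter peaks named for them include some at internal TSSs. Those of CCND3, ERCC1 and KRT8 lay 109017, 58277 and 46361 bp from the 5' end. The highest of these lists, WNT genes and intestinal epithelium, stood at percentiles 59.8 and 68.8 with gene 5' ends alone. Among signalling genes, 13 of 24 WNT pathway genes and targets (54.2%, percentile 96.7) had a promoter peak, led by AXIN1 (fold 6.48), CTNNB1, the beta-catenin gene (5.89), TCF7 (5.70) and NOTUM (5.55). In EGFR-RAS-MAPK signalling, 13 of 29 did (44.8%, percentile 81.0), led by HRAS (6.08), ERBB3 (5.32), MAP2K2 (5.22) and AKT1 (4.96). TNS1, which codes for tensin 1, had 2 promoter peaks, and the one with the higher fold, 4.62, lay near an internal TSS. The summit of that peak lay 175233 bp from the 5' end of the gene. EGFR had no peak at its promoters or in its body.

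Of genes for growth and metabolism, 13 of 32 cell cycle genes (percentile 66.1) had a promoter peak, with CCNE2 highest (7.03), then PLK1 (6.03), CCND3 (5.58) and MCM4 (5.23). Of 78 cytosolic ribosomal protein genes, 29 did (percentile 54.9), led by RPL32 (7.85), RPS10 (6.92), RPLP2 (6.27) and RPL22 (6.18). Oxidative phosphorylation had 11 of 38 (percentile 27.2), with ATP5F1C at 6.10, COX4I1 at 5.89 and ATP5MC1 at 5.23. Methionine and one-carbon metabolism had 8 of 19 (percentile 71.9), with SHMT1 at 7.07, PHGDH at 6.51, AHCYL1 at 6.09 and MTRR at 5.89. DNA repair had 11 of 33 (percentile 42.7), with ERCC1 at 8.19, FANCA at 5.71, LIG1 at 5.09 and RAD52 at 4.71. Housekeeping genes had 13 of 31 (percentile 81.3), with GUSB at 7.66, TUBA1B at 7.31, EEF1A1 at 6.48 and GPI at 6.31.

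Among genes of cell types, intestinal epithelium, the tissue of origin of the line, had 12 of 27 genes with a promoter peak (44.4%, percentile 96.5), led by the keratin gene KRT8 (7.41), the villin gene VIL1 (6.46), KRT19 (5.93) and LGALS4 (5.67). Liver genes had 1 of 22 (percentile 4.36), the peak of SERPINA1 (3.95). Neuronal genes had 7 of 22 (percentile 58.1), with GRIN1 at 8.02, MBP at 5.47, SLC17A7 at 5.24 and GFAP at 4.76. Blood and immune genes also had 7 of 22 (percentile 91.8), with ZAP70 at 4.68, LCK at 4.47 and CD4 at 3.94. Muscle genes had 6 of 22 (percentile 57.0), with TNNI3 at 4.92, RYR1 at 4.45, TNNT2 at 4.36 and TNNI2 at 4.23. Fibroblast and endothelial genes had 4 of 18 (percentile 36.9), namely COL1A1 at 5.75, VWF at 4.64, PDGFRB at 4.31 and CDH5 at 3.94. Interferon and antigen presentation genes had 5 of 28 (percentile 11.3), with ISG15 at 6.42, NLRC5 at 5.24, IRF3 at 4.56 and B2M at 4.34. Developmental transcription factors had 18 of 60 (percentile 20.4), with HOXA2 at 8.11, TBX1 at 6.52 and HOXA9 at 5.89. Within 500 bp of a TSS their share fell to 11.7%, below the matched range (percentile 0.32).

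**Figure D5:**
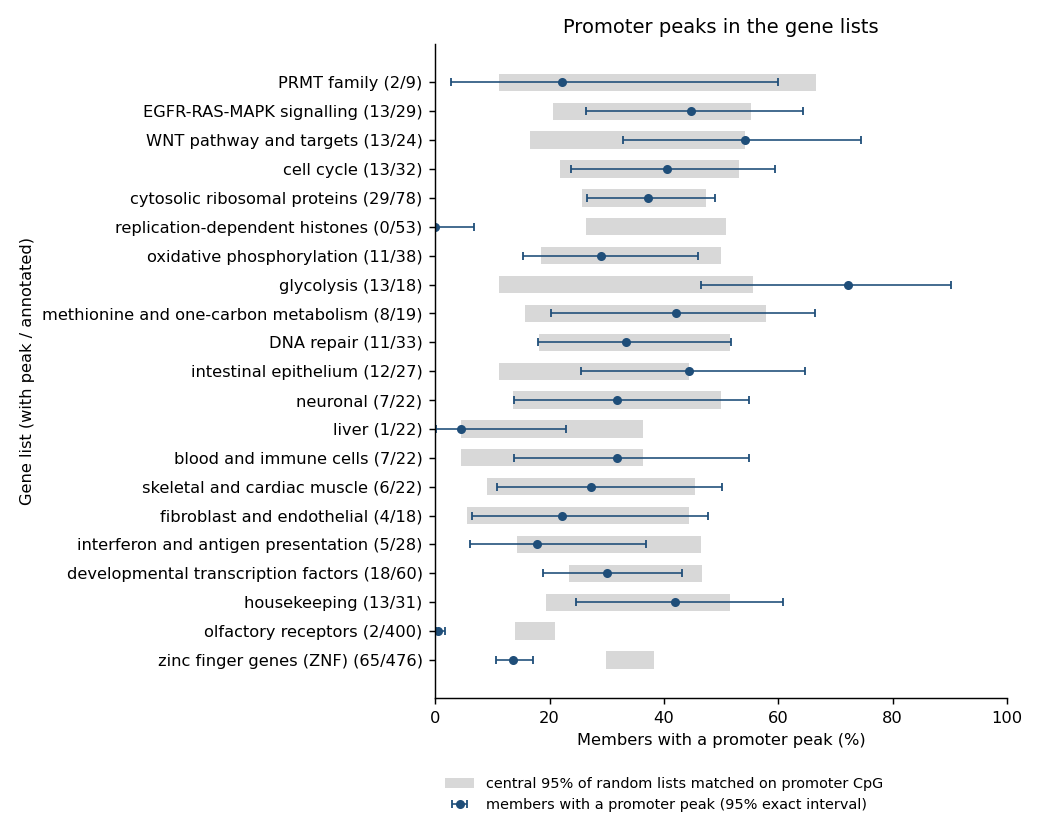
Share of members with a promoter peak (x axis, percent) for each gene list (y axis), as points with 95% exact intervals, over grey bars for the central 95% of random lists matched on promoter CpG content. Glycolysis lies above its bar at 72.2%, and replication-dependent histones, olfactory receptors and zinc finger genes lie below theirs.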

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

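The placements matched on GC and CpG were added after the data were first examined, and the tests of GC content downstream of the TSS, of GC content by chromosome, of background depth and of short repeated sequence were chosen only after the results were seen. The peak list held 4 peaks on mitochondrial DNA, which no comparison of the report used, and this signal outside the main measurement is the reason for listing them. They lay at 3141 to 3551, 3697 to 3937, 15680 to 15891 and 16042 to 16267, with folds of 3.47, 3.66, 4.77 and 3.33 and pileups of 22, 15, 16 and 14 fragments. Mitochondrial DNA carries no histones.

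Promoters held 30.3% of summits, and near canonical TSSs the summits lay downstream by a ratio of 4.47. The highest promoter share among 100 placements matched on GC was 23%, and 22.2% with CpG count also matched. These placements were not kept out of repeated sequence. Central 32-mers had more than 1 copy at 17.8% of random positions and 4.32% of peaks. What this adds to the remaining 1.35 times was not tested, so the shares do not decide whether GC content is the whole source. On the downstream side, GC content would give a ratio of 1.40, below the lower bound of 4.06. This argues against GC content alone as the source of the downstream position. GC content could still account for much of the promoter excess, because matching lowered it from 4.95 to 1.35 times. Summits also exceeded the GC-based number 2 to 3 kb from canonical TSSs, so an excess over GC content is not particular to promoters. A nucleosome-poor stretch just upstream of the TSS, where no histone could carry the mark, is a candidate explanation for the 66 summits found there, but no biological explanation was tested, and with 1 antibody and no replicate a general signal of open or transcribed chromatin stays open.

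Taken by length, peak density was high on chromosomes 16, 17, 19 and 22 and lowest on X and 18. GC content as the whole source is argued against by the ratio of 1.82 that chromosome 17 kept after it was taken into account (1.77 to 1.88). The depth of the background is a candidate explanation: over the 23 chromosomes the GC-adjusted ratio rose with the median background of peaks at 54 to 62% GC (Pearson's r = 0.771, permutation p = 3e-05; Spearman's rho = 0.794, permutation p = 1e-05, the smallest that 100000 permutations can give). Without chromosomes 8 and X, the farthest from the median, r was 0.801 (permutation p = 3e-05) and rho 0.760 (permutation p = 6e-05). HCT116 is known for gains on the long arms of chromosomes 8, 10, 16 and 17, but whether the background, read at called peaks only, follows DNA copies was not tested. Depth is argued against as the whole source on chromosome 19. Its ratio of 1.57 (1.52 to 1.62) lay above the 1.11 that was highest among the others with its median background of 1.54. The commonest backgrounds are spaced by 0.512 fragments, so equal medians allow some difference in depth. No biological explanation was tested.

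None of the 10 peaks with the highest pileup lay at a promoter, and the highest, on chromosome 21 at 8219942 to 8220179, had 283 fragments over a background of 129 and a fold of 2.18. Near-identical copies within the assembly are argued against as the source for most of the 10, since the median number of copies of the central 32-mers was 1. More than 1 copy was found for 3 of them (30%, 6.67 to 65.2%). That interval includes the 17.8% of random positions and lies above the 4.32% of all peaks, so copies stay open for these 3. Copies within the assembly that differ at some bases are argued against for most of the 10 as well. With 10 peaks, a share like the 12.2% of 500 random positions is not excluded. A second copy of the sequence within 200 bp of the summit was found for 0 of the 10 peaks (up to 30.8%). Short repeated sequence is a candidate explanation: a median of 31.5% of the 32-mers in that sequence (11.4 to 50%) occurred more than once, while the median was 0 both for 500 sampled peaks and for the random positions. The 10 peaks had backgrounds of 3.07 to 129 fragments, against a median of 1.54 over all peaks. Some of the 10 lie side by side, as on chromosome 1 from 144102434 to 144104736. They are not independent draws, so the intervals given for the 10 are likely too narrow. Both counts of copies cover the assembled sequence only, so neither bears on copies missing from it. Such missing copies stay open, and no biological explanation was tested.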

How the results depend on the processing

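Alternatives matched on GC, CpG count, promoter length or chromosome, the removal of multi-copy peaks, the removal of chromosomes 8, 10, 16 and 17, and the random share at gene 5' ends were chosen after seeing the data. No paired analysis was possible because each group held 1 library, and leaving out a replicate was not possible for the same reason. The filter on repeats and placement outside repeats were not run, since the reference used here has 0 lower-case bases. Depth set the lowest pileup that was called, from 5 fragments where the background was under 0.8 to 11 at 2.8 to 3.3, where the lowest fold fell from 3.35 to 2.83, so sites with a fold under 3.35 were not detectable where the background was under 0.8. Among the main values of each comparison, 53 alternatives left the value within its interval (or within 1.5 times for counts) and 65 moved it; of the values for single lists, chromosomes and classes, 331 stayed, 140 moved and 10 crossed 1. Stricter sets and merging change values by their construction; for the others the cause was not tested.

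With a −log10 q of 5 or more, 1280 peaks remained, the promoter share was 46.6%, 611 genes had a promoter peak, median folds were 6.42 at promoters and 6.31 in intergenic sequence, shares were 0.312% for 5' UTRs, 2.97% for non-coding exons, 29.6% for introns and 11.2% for intergenic sequence, GC content was 63.0%, and the ratios of chromosomes 17, 19 and X were 5.68, 6.42 and 0.0147. With a fold of 4 or more, these were 19691 peaks, 32% at promoters, median folds of 4.72 and 4.64, shares of 4.17% for 3' UTRs, 4.12% for coding sequence and 38.8% for introns, 59.2% GC, and ratios of 3.57 for chromosome 17 and 5.49 for chromosome 19. The 50% of peaks with the higher −log10 q gave 16679 peaks, 33.6% at promoters, 4152 genes, median folds of 4.80 and 4.79, shares of 4.63% for coding sequence, 38.2% for introns and 15.3% for intergenic sequence, 60.3% GC, ratios of 4.49, 5.68 and 0.0778, and 2 lists above the matched range. Merging gave 28.7% at promoters, median folds of 4.39 and 4.21, shares of 4.32% for 3' UTRs, 41.1% for introns and 18.1% for intergenic sequence, and ratios of 3.6 for chromosome 17 and 4.90 for chromosome 19.

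The promoter share was 19.8% within 500 bp, 49.0% within 3 kb, 32% with any overlap, 31.3% without multi-copy peaks and 11.9% with gene 5' ends alone, where 3829 genes had a peak. Its ratio to random placement was 1.35 with GC matching, 1.40 with GC and CpG matching and 6.51 with gene 5' ends alone, the last without GC matching. Lists above the matched range, 1 in the report, numbered 2 within 500 bp, 3 within 3 kb, 0 with gene 5' ends alone, 2 without matching and 2 with matching on CpG and gene length (those below numbered 2 to 4 in the settings run). Over 15 settings, olfactory receptors and ZNF genes stayed below the matched range in 15 and histone genes in 14, and glycolysis stayed above it in 14; WNT and liver genes stayed inside it in 11 and 10. Intestinal genes went above it within 3 kb (percentile 99.2) and housekeeping genes within 500 bp (97.8), where developmental transcription factors went below (0.32). GC content over the whole peak was 61.3%. Expected by gene number, chromosomes 17, 19 and X had ratios of 1.91, 1.42 and 0.123, with chromosome 22 highest (2.004) and chromosome 16 at 1.75, and by GC content those of 17, 19 and X were 1.82, 1.57 and 0.175. Ratios crossed 1 by gene number for chromosomes 1 (0.936), 8 (1.20), 10 (1.03) and 11 (0.875), by GC content for 8 (1.05), 12 (1.04) and 20 (0.985), and with a −log10 q of 5 or more for 8 (1.13) and 20 (0.818). Non-coding exons went from above random to 0.854 with GC matching.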

Other observations

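All values in this part were chosen after the data were seen. Some genes carried many peaks along their bodies. GSE1 on chromosome 16 had 131 peaks over 507 kb, and SEPTIN9 on chromosome 17 had 67 over 220 kb. BAIAP2 (47 peaks) and BAHCC1 (45), also on chromosome 17, and ZC3H3 (44) and PLEC (39) on chromosome 8 came next with PIEZO1 on chromosome 16 (42), and BAHCC1 and PLEC had 6.35 and 6.33 peaks per 10 kb. The genes named here lie where the background at called peaks was high. Its median was 2.75 fragments on chromosome 16 from 85 to 90 Mb, and 3.06 on chromosome 8 from 140 to 145 Mb. On chromosome 17 it was 2.56 from 75 to 80 Mb and 2.81 from 80 to 83.3 Mb. The median over all peaks was 1.54. Whether the counts follow regional depth or DNA copies was not tested. The counts therefore do not show marking particular to these genes. Of 19970 protein-coding genes, 9087 had at least 1 peak in the body.

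The windows of 5 Mb with the most peaks relative to GC content, among those with over 100 peaks, were mostly on chromosome 17. From 80 to 83.3 Mb there were 800 peaks, 2.76 times the number expected from GC content, at a median background of 2.81 fragments, and from 75 to 80 Mb there were 761, also 2.76 times, at 2.56. The windows of this chromosome from 50 to 55 Mb and from 45 to 50 Mb had 162 and 296 peaks (2.71 and 2.28 times, backgrounds 2.43 and 1.88). Chromosome 19 from 45 to 50 Mb had 573 peaks (2.26 times) at a background of 1.54. Chromosome 10 from 100 to 105 Mb had 254 peaks (2.34 times, background 2.05), while the whole chromosome had 0.806 of the expected number. Chromosome 16 from 85 to 90 Mb, which holds GSE1, had 760 peaks (2.07 times, background 2.75). A high background did not always go with an excess: the first 5 Mb of chromosomes 1 and 11 had backgrounds of 2.04 and 2.05 with ratios of 1.07 and 1.01.

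Among genes that do not code for proteins and lie over 2 kb from every protein-coding TSS, 4.42% of 13710 long non-coding RNA genes (95% exact interval 4.08 to 4.78%) and 7.33% of 1351 microRNA genes (6 to 8.85%) had a summit within 1 kb of a TSS. The share of random positions with a summit within 1 kb was 1.94%. These positions were weighted by chromosome length and not matched on GC content. They were also not kept away from protein-coding TSSs as the genes were, so the shares of genes are not set against like positions. The share was 0.916% for small nuclear RNA genes (0.524 to 1.48%), and none of 46 ribosomal RNA genes had a summit, which allows a share of up to 7.71%.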
